A study of Homo sapiens with 6 samples.

How the data were processed

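The data are RNA-seq libraries of MRC-5 fibroblasts, 3 from cells kept quiescent by contact inhibition for 9 days and 3 from young cells, all at population doubling 32. Per the labels' protocols, total RNA was made into libraries with the TruSeq RNA Library Preparation Kit v2, a kit that does not mark the strand. Per the submitters' processing notes, the processing involved bcl2fastq 1.8.4, STAR 2.4.1d, featureCounts 1.4.6-p4 and GRCh38. The authors deposited a table of raw read counts per gene, not normalised, with 60675 Ensembl genes and 1 column per library. They also deposited RPKM values, which are counts scaled by gene length and by a read total, for the same genes and libraries. The read length, the strand setting, the treatment of reads with several matches and the annotation release are not given in the sources used here. Per the labels, the young libraries are a reanalysis of libraries of an earlier series.

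The quiescent columns carry the titles of their samples. The 3 young columns were assigned to the young group because the labels of all 6 samples name the same tables and these 3 columns share another name, but which young sample each is could not be read from its name. They are called young library 1.0, 1.1 and 1.2, and the numbers pair nothing. Total counts per library ranged from 18661639 to 29433764 (young 28534800 ± 1450910, quiescent 20177000 ± 2078330, SD, n = 3). Intervals from counts cover counting error only, since the reads carry no molecular identifiers. Of the gene IDs, 57055 had an entry in GENCODE 29 on GRCh38, from which symbols, gene types and 1-based coordinates were taken, and 80 tested genes had none.

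Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, scaled with TMM factors, fitted by the robust quasi-likelihood model with group as the only term and tested with glmQLFTest. P-values were adjusted by Benjamini-Hochberg over the 15568 genes kept. Every adjusted p of a single gene is from this edgeR test unless another is named. The biological coefficient of variation was 3.84%, and TMM factors were 0.940 ± 0.0136 in young and 1.06 ± 0.00533 in quiescent libraries. CPM values use these factors, with a prior count of 2 for log2 CPM. Standard errors of fold changes are from the same fit. For a gene with 1 to 3 reads in a group, a ratio with an exact binomial 95% interval replaces the fitted fold. Libraries were compared by Pearson's r, by principal components and by a chi-square test of counts over genes with a summed count of at least 20.

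Gene lists were tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01, for lists with at least 5 measured members, and adjusted over the lists. The calls were repeated with the correlation estimated for each list and with fry. The 46 lists cover the cell cycle, matrix, cytoskeleton, signalling, metabolism, stress, markers of other cell types and RNA selection. They were fixed before the data were examined, as were the design, the alternatives and the rule for named genes.

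The rule named 25 genes fixed in advance. It also named the 8 largest rises and 8 largest falls at adjusted p under 0.05 among genes whose 3 and 3 values did not overlap, with a mean CPM of at least 10 in the higher group, reads in both groups and a symbol other than a clone or locus name; sex-linked check genes were excluded. For each list it named the 2 members with the largest called change at a mean CPM of at least 1, or else the most abundant, and the largest called change in the minority direction. Members of lists with few measured genes, and the genes and families of the closing section, were named after their values were seen. Some genes that the rule names, and 1 list with its members, are counted in the totals but not reported here.

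The tests were tried on simulated counts drawn from the means and library sizes of these libraries, for quiescent against young over 15338 genes. At adjusted p under 0.05, edgeR found 83.1% of 65 genes changed 1.5-fold, 84.8% of 66 changed 2-fold and 100% of 66 changed 4-fold. Of its 194 called genes, 9.28% had not been changed, which is above the share that a threshold of 0.05 is meant to allow. DESeq2 1.42.0 found 80.6%, 76.1% and 98.5%, with 3.95% of called genes unchanged. In the simulation of lists, over 15358 genes, camera called a list shifted by 0.5 in log2 and 1 of the other lists. Genes were drawn independently of each other and few were changed, unlike in these libraries. The simulations therefore cannot check the preset correlation or the scaling factors.

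The alternatives were DESeq2 size factors, library size alone, upper-quartile factors, no filter on low counts, CPM of at least 1 in at least 3 libraries, DESeq2's Wald test, limma-voom, limma on the deposited RPKM as log2(RPKM + 1) and log2(RPKM + 0.1), removal of the gene length trend, omission of the 50 most abundant and the mitochondrial genes, and omission of each library in turn. Omission of pseudogenes and removal of the GC trend were added after seeing the data. The deposited RPKM values were not used for any result outside these alternatives, since the read total behind them changes from gene to gene. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.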

Results

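RNA-seq counts per gene were examined for 6 libraries of MRC-5, an established line of human fetal lung fibroblasts with a finite replicative lifespan. In 3 of the libraries the cells had been held in quiescence, a reversible arrest outside the cell cycle, by 9 days of contact inhibition. The other 3 came from cells that the labels call young, and both groups were at population doubling 32. Total counts were 26860981, 29309684 and 29433764 in the young libraries, here called 1.0, 1.1 and 1.2, and 19323010, 22546237 and 18661639 in the quiescent ones. Of 60675 gene entries, 31386 had a read in any library and 15568 were abundant enough to be tested. Within each group, log2 CPM (counts scaled to a common library total) correlated across genes with Pearson's r of 0.9949 to 0.9957, and between groups r was 0.949 to 0.954; genes are not independent replicates. The first principal component of the 500 most variable genes held 95.9% of their variance and parted the groups. No pair of libraries agreed within sampling noise. The chi-square per degree of freedom was 1.48 to 1.98 between quiescent libraries and 3.43 to 8.83 between young ones, which therefore differed more among themselves. The young libraries were taken over from an earlier series, so library set and growth state coincide and cannot be told apart in any difference given here. The labels do not say that the 3 libraries of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

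The comparison asks how the transcripts of contact-inhibited fibroblasts differ from those of young ones. The arrested cells held far less mRNA for cell division: -3.37 ± 0.15 (SE) in log2 for MKI67, the proliferation antigen Ki-67, and -3.00 ± 0.06 for CCNB1, the cyclin that drives entry into mitosis. Most measured genes of the collagens (19 of 24), the contractile cytoskeleton (32 of 33) and glycolysis (20 of 24) were lower. More genes were higher than lower among complement (13 of 20 higher), lysosome and autophagy (32 of 53), interferon response (22 of 36) and FOXO-linked genes (16 of 27). The test of each list stands with its account. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 11064 of the 15568 genes (71.1%) changed at adjusted p under 0.05, 5412 higher and 5652 lower in quiescence. At least 2-fold, 1398 rose and 1297 fell, 2695 in all. The 3 quiescent and 3 young values did not overlap in 73.5% of genes, where chance gives 10%. The split by direction depended on scaling. With library size alone, the median of all tested genes moved from 0.00 to 0.18 in log2, and 7568 genes rose while 3889 fell.

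Among the 8 largest rises, FMO2, a flavin-containing monooxygenase of lung, rose from 0.772 ± 0.0629 to 62.0 ± 3.93 CPM (SD, n = 3 per group), which was 79.7-fold (adjusted p = 1.28e-25). A2M, the protease inhibitor alpha-2-macroglobulin, rose from 110.3 ± 7.35 to 3361 ± 300.1 CPM, 30.5-fold (adjusted p = 3.26e-15), and was by far the most abundant of the 8. ST8SIA4, a polysialyltransferase, rose by 5.44 ± 0.16 (SE) in log2, and GUCY1A1, a subunit of soluble guanylate cyclase, by 5.15 ± 0.19. TNFSF18, the ligand of the receptor GITR, rose by 5.06 ± 0.09, complement component C3 by 5.02 ± 0.11, tenascin X (TNXB) by 4.89 ± 0.17 and the chitinase-like protein CHI3L1 by 4.89 ± 0.06. The value of TNXB is uncertain, since part of the gene has a near-identical copy beside it. On GRCh38 these genes include FMO2 (ENSG00000094963) on chromosome 1 from 171185208 to 171211230, A2M (ENSG00000175899) on chromosome 12 from 9067664 to 9116229 and CHI3L1 (ENSG00000133048) on chromosome 1 from 203178931 to 203186749.

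Among the 8 largest falls, KISS1, which encodes the peptide kisspeptin, had 1040 reads in the young libraries and 2 in the quiescent ones, a ratio of 416 with a 95% counting interval of 115 to 3443. Both of those reads came from quiescent replicate 2. HBE1, an embryonic globin gene, fell from 20.3 ± 1.99 to 0.442 ± 0.126 CPM (adjusted p = 1.45e-20), a value left uncertain by its similarity to other globin genes. Its gene model also spans chromosome 11 from 5268345 to 5505652. Since the kit does not mark the strand, its reads cannot be told from those of genes overlapping on the opposite strand. SERPINB7, a serpin, fell by 28.2-fold and LRRC15, a membrane protein of activated fibroblasts, by 21.5-fold. S100A4, a calcium-binding protein also called fibroblast-specific protein, fell from 52.0 ± 4.02 to 3.51 ± 0.471 CPM (adjusted p = 4.35e-22). The kinase gene WNK4 changed by -3.85 ± 0.11 and the ligand gene WNT16 by -3.82 ± 0.16 in log2. NR4A1, an orphan nuclear receptor induced within minutes of stimulation, fell by 3.80 ± 0.29 on the log2 scale (adjusted p = 2.97e-04), with quiescent replicate 1 at 55.3 CPM and the other two at 28.8 and 29.7. KISS1 lies on chromosome 1 from 204190341 to 204196486 and LRRC15 on chromosome 3 from 194355247 to 194369743.

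**Figure D1:**
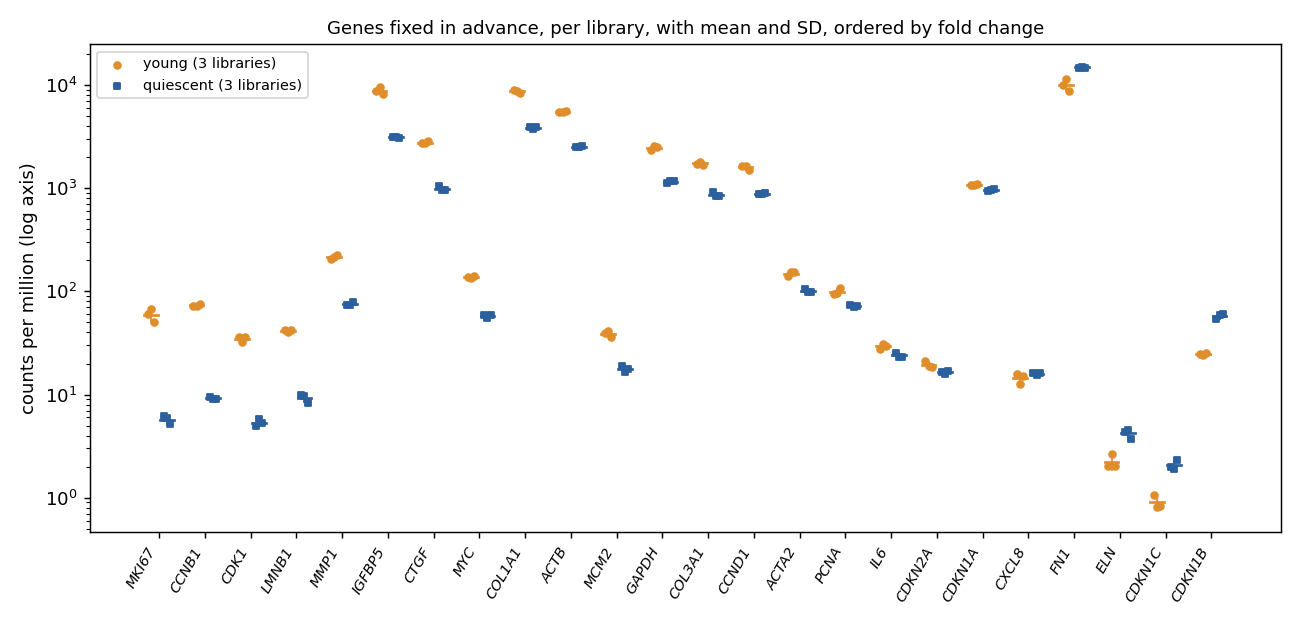
CPM (log axis) of 24 genes fixed in advance, ordered by fold change, in each of the 3 young (circles) and 3 quiescent (squares) libraries, with short horizontal lines at group means and vertical lines for the SD. MKI67 stood at 59.4 against 5.72 CPM at the left end and CDKN1B at 24.9 against 57.6 CPM at the right.

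Of the 46 gene lists fixed before the data were examined, 42 had at least 5 measured members. The camera test, which sets a list against all other genes with a preset correlation of 0.01 between members, called 26 of them, 18 lower and 8 higher in quiescence. With the correlation estimated for each list, 0 of 42 were called and 11 had an unadjusted p under 0.05. The fry test, which does not compare a list with other genes, found 38 lists moving one way on balance and 42 changing in either direction. Counts of members that rose or fell are from the per-gene test over all genes, and those adjusted over the list alone were equal in 43 of 46 lists. With library-size scaling, the medians of other matrix proteins, TGF-beta and BMP response, hypoxia response, MHC class I, lung fibroblast identity, ribosome biogenesis and cytosolic ribosomal proteins turned from below to above 0.

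Every one of the 39 measured mitosis genes fell at least 2-fold, with a median log2 fold change of -3.17, which left 11.1% of the young level (adjusted p = 1.14e-18 by camera, and adjusted p = 0.0781 with an estimated correlation). BIRC5, the inhibitor of apoptosis survivin, fell from 41.5 ± 2.08 to 3.39 ± 0.349 CPM (SD, n = 3), and KIF2C, a kinesin of the centromere, from 35.9 ± 0.906 to 2.94 ± 0.356 CPM. MKI67 fell from 59.4 ± 8.38 to 5.72 ± 0.522 CPM (adjusted p = 5.71e-07), CCNB1 from 73.6 ± 1.62 to 9.20 ± 0.219 CPM (adjusted p = 4.12e-24) and the mitotic kinase CDK1 from 34.9 ± 1.96 to 5.34 ± 0.402 CPM (adjusted p = 1.77e-20). Of the DNA replication genes, 36 of 37 fell and 0 rose, with a median of -1.12 or 46.0% of the young level (adjusted p = 7.15e-12 by camera, and adjusted p = 0.0639 with an estimated correlation). The list medians differed by 2.05 in log2, with a 95% bootstrap interval over genes of 1.67 to 2.36. Thymidine kinase TK1 fell 12.3-fold and the ribonucleotide reductase subunit RRM2 8.89-fold. The replicative helicase subunit MCM2 fell by 1.12 ± 0.06 (SE) in log2 and the sliding clamp PCNA from 98.9 ± 7.10 to 71.6 ± 1.63 CPM (adjusted p = 3.65e-09).

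Genes of homologous recombination and Fanconi repair had a median of -1.18, 22 of 25 fell and 1 rose (adjusted p = 1.31e-06 by camera, and adjusted p = 0.0769 with an estimated correlation). RAD54L changed by -2.65 ± 0.16 and RAD51AP1 by -2.62 ± 0.12 in log2, while PALB2, the partner of BRCA2, rose by 0.70 ± 0.07. Among chromatin factors tied to proliferation, 26 of 31 fell and 0 rose, with a median of -0.85 (adjusted p = 7.82e-08 by camera, and adjusted p = 0.0769 with an estimated correlation). The condensin subunits NCAPG and NCAPH stood at -2.92 ± 0.09 and -2.74 ± 0.11, and LMNB1, lamin B1 of the nuclear envelope, fell from 41.5 ± 1.26 to 9.31 ± 0.909 CPM (adjusted p = 1.03e-19). In the list of G1 cyclins, cyclin-dependent kinases, E2F factors and pocket proteins, 16 of 27 fell and 7 rose (adjusted p = 0.0277 by camera, and adjusted p = 0.181 with an estimated correlation). MYBL2 (-3.53 ± 0.10) and FOXM1 (-2.71 ± 0.07), transcription factors of the late cell cycle, fell, as did cyclin D1, CCND1, from 1603 ± 83.1 to 885 ± 6.56 CPM and MYC from 139 ± 3.13 to 58.0 ± 1.85 CPM. Cyclin D2, CCND2, rose from 17.1 ± 1.35 to 34.5 ± 0.574 CPM (adjusted p = 1.01e-13).

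The CDK inhibitors went both ways. All 8 changed, 3 up and 5 down, or 3 up and 2 down with library-size scaling, and the list was not called (adjusted p = 0.653 by camera). CDKN1B, p27, rose from 24.9 ± 0.594 to 57.6 ± 3.28 CPM (adjusted p = 1.03e-16) and CDKN1C, p57, rose from 0.900 ± 0.140 to 2.06 ± 0.226 CPM (adjusted p = 2.01e-05). CDKN3 (-2.92 ± 0.13), a phosphatase named among the inhibitors that peaks in dividing cells, and CDKN2C, p18 (-1.69 ± 0.09), fell. CDKN2A, the locus of p16, changed by -0.25 ± 0.07 (adjusted p = 0.00204) but by -0.07 with library-size scaling (adjusted p = 0.364). CDKN1A, p21, stood at -0.16 ± 0.04 (adjusted p = 6.65e-04), and its sign turned with library-size scaling, to 0.02.

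Collagen mRNA was lower in quiescence: 19 of 24 measured collagen genes fell and 3 rose, with a median of -0.83 (adjusted p = 1.12e-04 by camera, and adjusted p = 0.455 with an estimated correlation). COL1A1 fell from 8779.6 ± 309 to 3879.7 ± 109 CPM (adjusted p = 1.44e-18) and COL3A1 from 1741 ± 55.5 to 869.6 ± 36.8 CPM (adjusted p = 3.90e-17). COL21A1 rose from 0.511 ± 0.0805 to 4.59 ± 0.264 CPM and COL14A1, which binds to the surface of fibrils, by 2.79 ± 0.05 in log2. Of the enzymes and chaperones that process and crosslink collagen, 19 of 23 fell and 2 rose (adjusted p = 7.03e-06 by camera, and adjusted p = 0.143 with an estimated correlation). The lysyl oxidase homologues LOXL3 (-2.04 ± 0.04) and LOXL2 (-1.65 ± 0.04) fell and the prolyl hydroxylase subunit P4HA3 (0.87 ± 0.09) rose. Other matrix proteins went both ways, 19 up and 22 down among 46, or 23 up and 15 down with library-size scaling. Their median was -0.04 (0.14 with library-size scaling), their mean 0.39 and camera's direction up, with no call (adjusted p = 0.629). FMOD, the collagen-binding proteoglycan fibromodulin, rose from 16.3 ± 1.62 to 289 ± 13.6 CPM (adjusted p = 1.70e-24), elastin (ELN) from 2.21 ± 0.356 to 4.19 ± 0.406 CPM (adjusted p = 5.81e-06) and fibronectin (FN1) from 10143 ± 1396 to 14861 ± 268 CPM (adjusted p = 0.00195). Matrix proteases and their inhibitors had 12 of 28 up and 15 down without a call; camera's direction was down and fry's up (adjusted p = 0.759). Gelatinase A, MMP2, rose from 893 ± 24.0 to 2619 ± 36.0 CPM, interstitial collagenase MMP1 fell from 216 ± 11.0 to 75.5 ± 3.22 CPM (adjusted p = 3.95e-20), and ADAMTS6 (-2.53 ± 0.11) and ADAMTSL1 (-2.46 ± 0.11) fell.

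In the contractile cytoskeleton, 32 of 33 genes fell and 0 rose, with a median of -0.68 (adjusted p = 1.29e-10 by camera, and adjusted p = 0.0769 with an estimated correlation). The smooth muscle actin ACTG2 fell from 487 ± 11.2 to 87.5 ± 3.80 CPM, transgelin (TAGLN) from 1601 ± 67.8 to 405 ± 15.8 CPM, ACTA2 from 149 ± 6.97 to 101 ± 3.97 CPM (adjusted p = 1.58e-11) and beta-actin (ACTB) from 5521 ± 60.4 to 2542 ± 28.5 CPM (adjusted p = 9.06e-19). Actin genes share sequence with each other and with pseudogenes, so these values carry that uncertainty. Markers of pericytes and smooth muscle, 3 of which are also in the contractile list, had 10 of 11 lower and 0 higher, with SYNPO2 at -1.82 ± 0.08 (adjusted p = 6.83e-05 by camera, and adjusted p = 0.143 with an estimated correlation). Targets of YAP and TAZ, coactivators that respond to cell density and tension, had 17 of 23 lower and 2 higher, or 17 lower and 4 higher adjusted over the list alone (adjusted p = 7.02e-04 by camera, and adjusted p = 0.181 with an estimated correlation). Connective tissue growth factor (CTGF) fell from 2776 ± 79.4 to 995 ± 47.5 CPM (adjusted p = 1.68e-20), tissue factor (F3) from 1769.8 ± 54.3 to 328 ± 6.20 CPM and NUAK2 by 4.57-fold, while ANKRD1 rose from 1.73 ± 0.253 to 3.83 ± 0.198 CPM. Genes of the TGF-beta and BMP response (9 up, 12 down of 26, adjusted p = 0.444) and the Wnt pathway (9 up, 12 down of 25, or 10 up and 9 down with library-size scaling, adjusted p = 0.587) were not called. HES1 (-3.46 ± 0.07) and ID4 (-2.06 ± 0.10) fell and the pseudoreceptor BAMBI (2.02 ± 0.07) rose in the former; in the latter WNT2 rose by 2.19 ± 0.08. For cell adhesion and junctions, 12 of 39 rose and 23 fell (adjusted p = 0.110, or 0.0350 with library-size scaling). VCAM1 rose from 13.2 ± 0.362 to 134 ± 2.76 CPM and integrin ITGB8 by 2.89 ± 0.05 in log2.

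Of 34 factors assigned to the secretory phenotype of senescent cells, 23 fell and 8 rose, with a median of -0.70 (adjusted p = 0.00142 by camera, and adjusted p = 0.143 with an estimated correlation). IGFBP5, an IGF-binding protein, fell from 8859 ± 618 to 3121 ± 42.8 CPM (adjusted p = 6.74e-20). Interleukin 6 (IL6) changed by -0.29 ± 0.06 (adjusted p = 1.38e-04) and by -0.11 with library-size scaling (adjusted p = 0.105). CXCL8 did not pass the test at 0.13 ± 0.08 (adjusted p = 0.137), but passed it at 0.31 with library-size scaling (adjusted p = 0.00168), at 0.20 with upper-quartile factors (0.0270) and at 0.20 without young library 1.0 (0.0442). The chemokines CXCL1 and CXCL5 rose from low levels, from 0.377 ± 0.141 to 5.58 ± 0.654 CPM and from 1.08 ± 0.258 to 7.18 ± 0.343 CPM. Complement genes had 13 of 20 higher and 6 lower, with a median of 0.60 (adjusted p = 0.0380 by camera, and adjusted p = 0.488 with an estimated correlation). C3 rose from 0.926 ± 0.157 to 30.1 ± 2.01 CPM (adjusted p = 1.02e-22), the serine protease C1S from 411 ± 13.2 to 1496 ± 19.7 CPM, and MASP1 of the lectin pathway fell from 157 ± 9.12 to 54.0 ± 1.22 CPM. The complement call ended with library-size scaling (adjusted p = 0.145), with a CPM minimum (0.0603), with length or GC trends removed (0.0509 and 0.0513) and without young library 1.1 (0.0563). Interferon response genes had 22 of 36 higher and 8 lower (adjusted p = 0.0159 by camera, and adjusted p = 0.143 with an estimated correlation), with HERC5 (3.54 ± 0.30) and IFIT2 (1.52 ± 0.08) up and GBP1 (-1.41 ± 0.05) down. MHC class I and antigen presentation showed 3 of 13 higher and 4 lower, or 7 higher and 1 lower with library-size scaling, with camera's direction down and fry's up (adjusted p = 0.911). Its HLA-B, one of a family of similar genes, rose by 0.43 ± 0.04 and the immunoproteasome subunit PSMB9 changed by -0.53 ± 0.16 (adjusted p = 0.00459), a call lost with library-size scaling (0.0504) and with DESeq2 (0.0531).

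**Figure D2:**
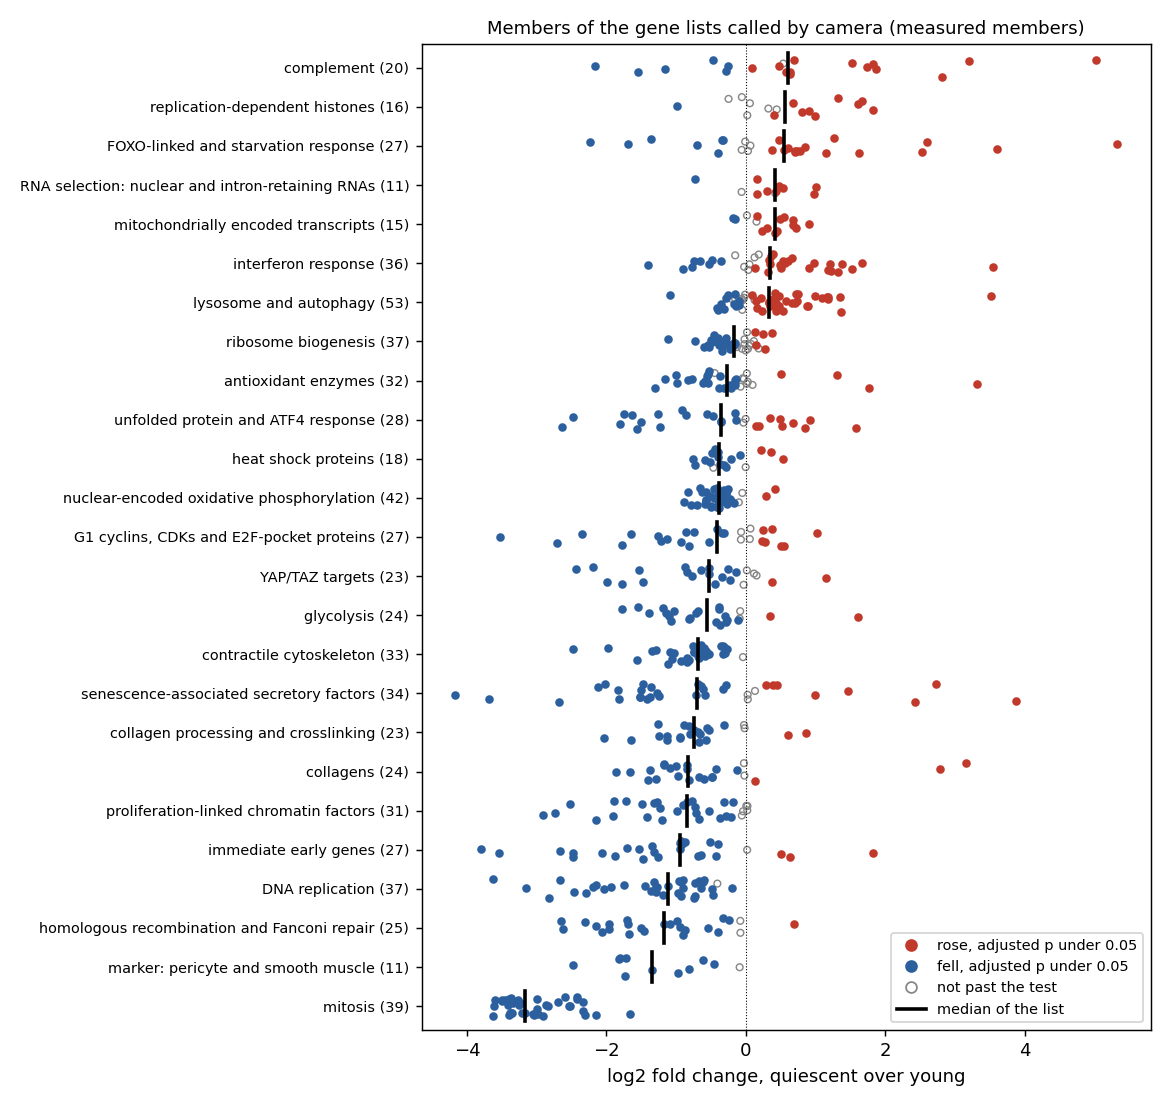
Log2 fold change (quiescent over young) of each measured member of 25 of the 26 gene lists called by camera, with the number of measured members after each name, filled points for members at adjusted p under 0.05 and a vertical bar at each list's median. Medians run from 0.60 for complement to -3.17 for mitosis, where all 39 members lie below 0.

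Glycolysis transcripts were lower, with 20 of 24 down, or 21 adjusted over the list alone, and 2 up (adjusted p = 1.87e-05 by camera, and adjusted p = 0.143 with an estimated correlation). The glucose transporter SLC2A1 fell from 354 ± 7.48 to 103 ± 4.96 CPM, GAPDH, which has many processed pseudogenes, from 2481 ± 92.2 to 1153 ± 33.6 CPM (adjusted p = 3.81e-18), and PFKFB2, a regulator of glycolytic flux, rose from 7.78 ± 0.789 to 23.7 ± 0.770 CPM. Nuclear-encoded oxidative phosphorylation showed small but shared falls, 37 of 42 down and 2 up with a median of -0.39 and no change of 2-fold (adjusted p = 4.37e-07 by camera, and adjusted p = 0.455 with an estimated correlation). COX8A stood at -0.89 ± 0.05, UQCRC1 at -0.82 ± 0.04 and NDUFB5 at 0.42 ± 0.05. Transcripts encoded by the mitochondrial genome went the other way, 11 of 15 up and 2 down (adjusted p = 0.0107 by camera, and adjusted p = 0.575 with an estimated correlation). MT-ND3 rose by 0.91 ± 0.04 and MT-ND5 by 0.72 ± 0.05; MT-CO2 stood at -0.18 ± 0.05 (adjusted p = 9.73e-04), and did not pass the test with library-size scaling (0.938) or with the length trend removed (0.835). Nuclear copies of mitochondrial genes leave these values uncertain. Mitochondrial genes took 4.63% ± 0.176 of counts in quiescent and 3.46% ± 0.127 in young libraries (SD, n = 3). Cholesterol synthesis and uptake (8 up, 7 down of 25, or 16 up and 5 down with library-size scaling) was not called (adjusted p = 0.569), with the squalene epoxidase gene SQLE (0.77 ± 0.04) up and PMVK (-0.45 ± 0.07) down. Fatty acid synthesis and storage (11 up, 3 down of 21, adjusted p = 0.109) was not called either, with DGAT2 (1.60 ± 0.22) and CD36 (1.52 ± 0.13) up and PPARG (-0.63 ± 0.04) down. Hypoxia response genes split 8 up and 11 down of 23, or 10 up and 8 down with library-size scaling (adjusted p = 0.629). PDK1, which restrains pyruvate oxidation, stood at -1.50 ± 0.07 and MXI1, a MYC antagonist, at 1.48 ± 0.06.

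Lysosome and autophagy genes had 32 of 53 higher and 12 lower, with a median of 0.33 (adjusted p = 0.00530 by camera, and adjusted p = 0.455 with an estimated correlation). Cathepsin K (CTSK) rose from 49.2 ± 2.79 to 562 ± 9.26 CPM (adjusted p = 4.43e-27) and the hexosaminidase subunit HEXA from 49.3 ± 1.18 to 127 ± 0.724 CPM, while cathepsin Z (CTSZ) fell from 211 ± 9.23 to 98.9 ± 2.97 CPM. Genes linked to FOXO factors and starvation had 16 of 27 higher and 7 lower (adjusted p = 0.0277 by camera, and adjusted p = 0.238 with an estimated correlation), a call that ended with library-size scaling (adjusted p = 0.0758). The proapoptotic BCL2L11 rose from 2.39 ± 0.170 to 14.5 ± 1.44 CPM, the ubiquitin ligase FBXO32 from 9.71 ± 0.579 to 55.7 ± 1.06 CPM, and the clock gene PER1 fell from 52.9 ± 4.22 to 11.3 ± 0.987 CPM. Antioxidant enzymes had 20 of 32 lower and 4 higher, or 15 lower and 9 higher with library-size scaling (adjusted p = 0.0171 by camera, and adjusted p = 0.575 with an estimated correlation). The members with the largest changes were among the 4: GPX3, a secreted glutathione peroxidase, rose from 5.06 ± 0.194 to 50.4 ± 0.780 CPM and the mitochondrial superoxide dismutase SOD2 from 248 ± 2.97 to 841 ± 27.4 CPM. Of the unfolded protein and ATF4 response, 17 of 28 fell and 9 rose (adjusted p = 0.0380 by camera, and adjusted p = 0.617 with an estimated correlation), with SDF2L1 at -2.64 ± 0.06, ATF3 at -2.47 ± 0.05 and DDIT4 at 1.58 ± 0.05. That call ended without quiescent replicate 1 (adjusted p = 0.0523) and with a CPM minimum (0.0509). Ribosome biogenesis had 21 of 37 lower and 5 higher (adjusted p = 0.0368 by camera, and adjusted p = 0.543 with an estimated correlation), with RRS1 at -1.11 ± 0.05, BOP1 at -0.73 ± 0.05 and UTP15 at 0.37 ± 0.06. It was lost without quiescent replicate 3 (adjusted p = 0.0567), with a CPM minimum (0.0603), with the GC trend removed (0.0513) and with library-size scaling (0.148), where 13 rose and 14 fell. Cytosolic ribosomal proteins, many with pseudogenes that share their reads, had 41 of 85 lower, or 40 adjusted over the list alone, and 14 higher (adjusted p = 0.137). This direction turned with library-size scaling, to 41 higher and 21 lower, and the list was called without young library 1.1 (adjusted p = 0.0438). RPL36A stood at -1.17 ± 0.11, RPL39L at -0.84 ± 0.11 and RPL39 at 0.73 ± 0.08.

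Immediate early genes, which growth factors and handling induce within minutes, had 23 of 27 lower and 3 higher, with a median of -0.94 (adjusted p = 7.03e-06 by camera, and adjusted p = 0.419 with an estimated correlation). NR4A2 fell from 134 ± 6.33 to 11.4 ± 0.495 CPM and EGR2 rose from 3.99 ± 0.154 to 14.1 ± 0.743 CPM. Heat shock proteins had 13 of 18 lower and 3 higher (adjusted p = 0.0277 by camera, and adjusted p = 0.488 with an estimated correlation), with the small heat shock proteins HSPB6 (-0.76 ± 0.05) and HSPB1 (-0.73 ± 0.04) down and HSPB8 (0.53 ± 0.06) up. Only 4 members of the metallothionein list were measured, a family of near-identical genes. Among them, MT1L is annotated as a transcribed pseudogene. MT1L (-2.30 ± 0.12), MT1E (-1.14 ± 0.08) and MT2A (-0.53 ± 0.05) fell, and MT1X stood at 0.11 (adjusted p = 0.666). Of 71 replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail and which resemble each other closely, only 16 were measured. Of these 16, 9 were higher and 1 lower (adjusted p = 0.0171 by camera, and adjusted p = 0.224 with an estimated correlation). These counts leave out most listed histone genes and do not describe histone mRNA as a whole. HIST1H4H rose from 1.08 ± 0.0618 to 3.87 ± 0.991 CPM and HIST3H2A from 2.29 ± 0.196 to 7.25 ± 0.584 CPM. Nuclear and intron-retaining RNAs had 8 of 11 higher and 1 lower (adjusted p = 0.0362 by camera, and adjusted p = 0.224 with an estimated correlation), a call lost with library-size scaling (adjusted p = 0.0646). OIP5-AS1 rose from 49.3 ± 0.754 to 98.9 ± 3.19 CPM, a value uncertain because the kit does not mark the strand and reads of genes that overlap on opposite strands cannot be told apart, and NEAT1 rose by 0.97 ± 0.06 in log2, while MALAT1 fell by 0.73 ± 0.04. Of the RNAs without a poly(A) tail, SNORA73B alone was measured, at 0.19 ± 0.18 (adjusted p = 0.345).

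Of 27 lung fibroblast identity genes, 24 were measured. Of these 24, 11 rose and 11 fell, or 13 rose and 8 fell with library-size scaling (adjusted p = 0.954 by camera). At least 2-fold, 4 rose and 5 fell. S100A4, a member of this list, fell by 3.89 ± 0.09 in log2. FGF10 was higher by 2.38 ± 0.23, from a low level of 0.807 ± 0.390 to 4.24 ± 0.657 CPM. Of the marker lists of other cell types that had enough measured members, camera called that of pericytes and smooth muscle and no other, and did not call it with an estimated correlation (adjusted p = 0.143). Measured were 8 of 20 listed epithelial markers, 7 of 16 endothelial, 9 of 15 cartilage and bone and 7 of 15 neural markers. The same held for 11 of 15 pericyte and smooth muscle, 2 of 18 blood cell and 4 of 14 adipocyte markers. Of the 8 measured epithelial markers, 1 rose and 5 fell (adjusted p = 0.199 by camera), with KRT19 at -3.56 ± 0.14 and MUC1 at 1.03 ± 0.09. Of 7 endothelial markers, 3 rose and 3 fell. Their median of 0.18 and mean of 0.30 were above 0, while camera's direction was down (adjusted p = 0.990). VWF rose from 0.803 ± 0.209 to 3.27 ± 0.277 CPM and KDR from 0.394 ± 0.236 to 3.10 ± 0.112 CPM, and ROBO4 fell from 4.11 ± 0.336 to 1.26 ± 0.218 CPM. Of 9 cartilage and bone markers, 2 rose and 5 fell (adjusted p = 0.207), with MATN3 at -1.98 ± 0.13, ALPL at -1.17 ± 0.06 and PHEX at 0.55 ± 0.20. PHEX lost its call without quiescent replicate 1 (adjusted p = 0.124), without young library 1.2 (0.0633) and with DESeq2 (0.154). Of 7 neural markers, 2 rose and 4 fell (adjusted p = 0.511), with nestin (NES) at -1.26 ± 0.04, TUBB3 at -0.61 ± 0.18 (adjusted p = 0.0625 with DESeq2) and MBP at 0.53 ± 0.09. Among blood cell markers, CORO1A (-3.95 ± 0.26) and CD14 (1.31 ± 0.20) were measured, the former at 3.45 to 0.213 CPM. Of the adipocyte markers, FABP4 (-1.13 ± 0.19) fell and so did PPARG, whereas LIPE (-0.33, adjusted p = 0.0547) and PLIN4 (-0.23, adjusted p = 0.372) did not pass the test.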

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

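The alternatives that omit pseudogenes and remove the GC trend were chosen after seeing the data, and the other alternatives before. Over all alternatives, 2781 of 2818 comparisons of a named gene kept their side of the threshold, and their direction where the gene was called. Of the others, 32 fell below the threshold, 4 passed it and 1 called gene turned. A change of direction in a gene called in neither fit counted as kept. SNORA73B, for example, went from 0.19 to -0.02 without young library 1.1 (adjusted p = 0.918). Most named genes were picked for a large called change in these same data, so keeping the call was likely and says little about other genes. The 25 genes fixed in advance were not counted apart. For gene lists, 597 of 672 comparisons stayed the same, 45 fell below the threshold, 30 passed it and 0 turned with a call. Here too a change of direction without a call counted as the same, and fry's test in either direction compared no direction. For example, matrix proteases and MHC class I were down by camera and up by fry, with no call by either. The called gene that turned was CDKN1A, at a log2 fold change of 0.0204 with library size alone (adjusted p = 0.625 by edgeR's quasi-likelihood test). Of the 11064 changed genes, 99.7% were called in the same direction with DESeq2 size factors, 99.2% with limma-voom, 83.9% with DESeq2's Wald test, and 84.1% with library size alone, where 6 were called in the opposite direction. Without 1 library, between 10439 and 11034 genes changed, and between 2789 and 2990 at least 2-fold.

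The share of changed genes that rose, 48.9% in the results above, was 66.1% with library size alone, 56.1% with upper-quartile factors, 46.1% without a filter, 50.3% with a CPM minimum, 45.9% with DESeq2's Wald test, 50.03% without the 50 most abundant and mitochondrial genes and 50.2% without pseudogenes. The move under the first 2 follows from the scaling itself. Genes changed at least 2-fold numbered 4085 without a filter, where more genes were tested. With the deposited RPKM, 7255 genes changed on the log2(RPKM + 1) scale, 1019 of them at least 2-fold and 38.4% of them upward, and 7354 with a pseudocount of 0.1, 2310 of them at least 2-fold and 38.9% of them upward; 70 and 68 genes were called opposite to the counts. With a correlation estimated for each list, 0 lists were called by camera (smallest adjusted p = 0.0639; 11 at an unadjusted p under 0.05; 38 by fry for 1 direction), and 42 changed in either direction by fry. On RPKM values, camera's calls of antioxidant enzymes (adjusted p = 0.147), interferon response (0.0501), ribosome biogenesis (0.161), heat shock proteins (0.245) and nuclear RNAs (0.232) were lost. Apart from the scaling, the filter and the RPKM values, the cause was not tested. No paired analysis was possible because the young columns carry no number that matches the labels, so the replicate block, alone or with the length correction, was not run.

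The 6 libraries can be split into 3 and 3 in 10 ways. All but the real split mix young and quiescent libraries on each side. Such splits widen the spread within a side and still hold part of the real difference, so they are not comparisons without a difference. The real split gave 11064 changed genes and the highest of the other 9 splits 0 by edgeR and 0 by limma-voom, with up to 56 genes at an unadjusted p under 0.05. At least 2-fold, it gave 2695 genes against 0. For camera, it gave 26 lists against 17, and each of the other splits gave at least 11. In all 3 cases 1 of the 10 splits, the real one, gave a result as large, and 10 splits are too few for a share under 0.05. Depth limits the genes of low count, which are the ones the choice of filter adds or removes.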

Other observations

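All gene families and the tests of the cycling-cell remainder, of recycled read totals and of pseudogenes against single young libraries and within a parent's copies were chosen after the values were seen. The counts and medians of the families are therefore descriptions, and no test of a family is given. Genes of cyclic GMP signalling were mostly higher in quiescence: 9 of 12 measured rose and 1 fell, with a median log2 fold change of 1.42. Both subunits of the main nitric oxide receptor rose, GUCY1A1 by 5.15 and GUCY1B1 by 3.08 in log2. So did the phosphodiesterase PDE3A, by 4.67, from 0.0994 to 2.66 CPM, and the natriuretic peptide clearance receptor NPR3, by 2.13; PDE1C fell by 0.70. Among beta protocadherins, cell adhesion genes of 1 cluster with similar sequences, 12 of 13 rose and 0 fell (median 1.52). Their levels were low. PCDHB11 rose by 3.04, from 0.121 to 1.08 CPM. PCDHB14, the most abundant of the 13, rose by 1.54, from 1.89 to 5.50 CPM. Cytochrome P450 genes had 10 of 14 higher and 1 lower (median 0.94). Alpha and beta tubulins, which are alike in sequence, had 10 of 11 lower and 0 higher (median -1.48), TUBA1A from 668 to 275 CPM and TUBB4B from 348 to 125 CPM. All these medians kept their sign under the 3 other scalings.

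Zinc finger genes with a ZNF symbol moved by little and mostly upward, 260 of 433 higher and 34 lower (median 0.38). Long intergenic RNAs had 206 of 434 higher and 62 lower (median 0.49), where abundance-matched sets of genes had a median of 0.17. Antisense RNAs, whose reads cannot be told apart from those of overlapping genes since the kit does not mark the strand, had 280 of 677 higher and 86 lower (median 0.36). Abundance-matched sets had a median of 0.20 for antisense RNAs and of 0.05 for zinc finger genes. Prostanoid synthesis and breakdown went both ways, 5 of 11 up and 5 down: PTGDS, the prostaglandin D synthase, rose by 4.38 in log2 to 313 CPM and PTGES by 1.94, while the cyclooxygenases PTGS1 and PTGS2 fell by 2.33 and by 1.44 on the log2 scale. Of 14 genes commonly used as references in quantitative PCR, some of them also in the glycolysis and contractile lists, 10 fell and 3 rose (median -0.52, or -0.34 with library-size scaling). RPLP0 stood at -0.01 (adjusted p = 0.904), or 0.17 with library-size scaling, and TBP and B2M rose by 0.24 and 0.28.

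Processed pseudogenes were lower in quiescence than the genes they were copied from: 259 of 405 pairs, with a median difference of -0.23 in log2, or -0.20 without the copies of EEF1A1; EEF1A1 itself stood at 0.01, while its 18 measured copies on 13 chromosomes all fell, with a median of -2.24, and 7 copies of GAPDH had a median of -3.28 against -1.11 for the gene. The size of the difference depended on the young library, being -0.11 against 1.0 alone, -0.35 against 1.1 and -0.17 against 1.2, and the share of counts on processed pseudogenes was 0.309% in young library 1.0, below the 0.314% to 0.318% of the quiescent ones, but 0.365% in 1.1 and 0.351% in 1.2. For the pseudogenes' own fold changes, a trend with abundance is argued against. Their median of -0.47 lay at percentile 0 of 10000 abundance-matched sets of genes other than pseudogenes (median 0.26, 95% of them from 0.16 to 0.35). The difference from the parent was not tested in this way. Across 255 parent genes, the difference was more negative where copies shared more 31-base words with the parent (Spearman's rho = -0.34, permutation p = 1e-05, the smallest 1e+05 permutations can give; genes are not independent replicates), and less so against young library 1.0 alone (-0.17), but among the copies of a single parent rho was 0.16 for EEF1A1, 0.29 for GAPDH and above 0 for 6 of 8 parents with at least 5 copies. Parent reads placed on copies differently from library to library are a candidate explanation that these values leave open, and whether transcription of the copies changed was not tested.

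Replication genes kept 46.0% of their young level at the median and mitosis genes 11.1%, a difference of 2.05 in log2 (95% bootstrap interval 1.67 to 2.36), and 26 replication genes lay above the highest mitosis gene. A remainder of cycling cells with the young profile, beside arrested cells that hold neither set of mRNAs, would leave the same share of both lists. Under those assumptions, which were not measured, the difference argues against such a remainder as the whole cause. The difference is also the observation that raised the question, so it is not a separate test. Removal of the gene length trend left the difference at 2.07, and removal of the GC trend at 2.14, so neither trend is likely to be the cause. The hypothesis that arrested cells may keep part of their replication mRNA stays open, as does a difference between the library sets, which cannot be told apart from growth state.

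The read total behind the deposited RPKM values changed from gene to gene. With totals that repeat every 14 genes in the quiescent and every 15 in the young columns, at least 91.8% of genes with a count of at least 50 matched the total of their place within 1%; the best cycle of another length matched at most 47.3%. This is consistent with a list of library totals recycled down the table. Other gene lengths are argued against, since 0% of 9788 genes had 1 ratio of implied to actual total in all 6 columns. The log2 ratio of quiescent to young RPKM was set against the ratio that each library's own total count would give. It was off by -0.30 at the median, with 0.5% of genes below -0.81 and as many above 0.40. These errors are not relative to the TMM factors used in the results above.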
